A study of Mus musculus with 18 samples.

How the data were processed

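The deposited barcode, gene and matrix tables were used, 18 libraries of UMI counts that the submitters made with Cell Ranger 3.0.2 on the GRCm38 mouse genome from 10x 3′ V2 libraries of polyadenylated RNA. Per the submitters' processing notes the values are raw UMI counts (unit: count), and the values themselves are whole numbers without a contradiction to that unit. Livers were perfused with collagenase H, the plasmid and Sleeping Beauty transposase were injected at a ratio of 10:1, and Hep and NPC fractions were separated by centrifugation, per the labels. All libraries listed 46078 mouse genes, and 4 Hep libraries (WT and SKO 10D-Myc, SKO 4W-Myc and WT 4W-Myc replicate 1) listed 1 further feature for human MYC. The other 14 libraries were counted without that feature, so human MYC was compared only among the 4. Of the gene identifiers 45143 were found in the annotation used for positions, which are given in GRCm38 coordinates.

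The 18 libraries held 52034 barcodes. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 40% mitochondrial counts. A doublet score was computed in each library from simulated doublets by the Scrublet approach, and the highest scores were removed at 0.8% of barcodes per 1000 barcodes, 1420 in all. Cells of all libraries were clustered together without batch correction by Leiden at resolution 1.0, which gave 41 clusters. Clusters were named from marker lists fixed before the data were examined, with the suffix -like, and a cluster without enough markers stayed unnamed. Hepatocyte-lineage cells are hepatocyte-like plus oncofetal hepatocyte-like cells.

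Counts were summed per library and class, with at least 20 cells per library, and each summed library was 1 unit of replication, so that cells were never replicates. Hepatocyte-lineage cells were tested in the 9 Hep libraries and immune classes in the 9 NPC libraries. edgeR was used with filterByExpr, TMM scaling, a model of stage (4 levels) plus genotype (2 levels), robust quasi-likelihood F tests and Benjamini-Hochberg correction at 0.05, which left 4 residual degrees of freedom. The 4 comparisons were SKO against WT over stages, and 10D-Myc against 10D-Vector, 4W-Myc against 0D-Ctrl and 10D-Vector against 0D-Ctrl over genotypes. They were made in 7 classes, 28 tests in all. Adjusted p in the report is that of edgeR unless DESeq2 is named. All fold changes are log2 of the former group over the latter. Only WT 4W-Myc had 2 libraries, so the residual spread came from these and from differences between the genotypes in their response to stage. In a fit that left out either of these libraries no group was replicated, and the spread came from those differences alone.

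Gene groups came from 29 lists fixed before the data were examined, tested by camera of limma with a preset correlation of 0.01 between genes (632 tests over classes and comparisons), with camera and an estimated correlation and with fry as alternatives. Beside genes passing over all genes tested, genes passing when adjusted over the list alone are given, and in brackets the former count stands before the latter.

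Named genes were chosen by a rule fixed before the data were examined: up to 12 higher and 12 lower genes with adjusted p under 0.05, ranked by fold change, with a mean of at least 30 CPM and the same direction in every matched pair (4 stages for genotype, with WT 4W-Myc as the mean, or both genotypes for stage). Predicted genes, mitochondrial, ribosomal protein, immunoglobulin variable and haemoglobin genes were left out. Up to 4 genes of each list were added, and Ptpn11, Myc, Ctnnb1, Afp, Gpc3, Glul, Axin2, Ccnd1, Mki67, Xist, Ddx3y and human MYC were always followed. Genes of hepatocyte-lineage cells over 10 times as high in an NPC class, and genes of NPC classes over 5 times as high in hepatocyte-lineage cells, were treated as possible free RNA and counted apart. At single stages the 10 highest and 10 lowest ratios were taken among genes with at least 100 UMIs and 50 CPM in the higher group, and at 4W-Myc with both WT libraries on the same side of SKO. Genes named from the fit without the library labelled WT 4W-Myc Hep replicate 2 were picked by the same rule applied after its values were seen. A level of 0 was set to 3 counts for a ratio given as at least N-fold. Intervals of levels, ratios and shares are exact 95% Poisson or binomial intervals.

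Cells in G2 or mitosis were those with at least 2 UMIs of 11 genes after thinning to 1000 UMIs, without cells below that depth. Shares of cells were compared between SKO and WT by the mean log-odds difference over the stages, with 0.5 added to counts, and an exact permutation test of genotype labels within stages. The tests were tried on simulated counts with added changes. For a log2 change of 2 between genotypes, edgeR recovered 29.0% of genes in hepatocyte-lineage cells (DESeq2 65.0%). Software was Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.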

Results

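Single-cell RNA profiles were collected from livers of C57BL/6 mice that were wild type (WT) or lacked Shp2 in hepatocytes (SKO). Shp2 is a phosphatase encoded by Ptpn11 that passes growth factor signals to the Ras and Erk pathway. Livers were taken without injection (0D-Ctrl), 10 days after injection of an empty vector (10D-Vector) or of a Myc plasmid (10D-Myc), and 4 weeks after the Myc injection (4W-Myc). In a hydrodynamic tail vein injection a large volume given rapidly carries plasmid into hepatocytes, and the Sleeping Beauty transposase given with it inserts the Myc transgene into the genome. The series asks what Shp2 and β-catenin contribute inside hepatocytes to liver tumours driven by Myc.

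Each liver preparation was separated by centrifugation into a hepatocyte fraction (Hep) and a non-parenchymal cell fraction (NPC). The 18 libraries fell into 16 groups, and only the WT 4W-Myc groups had 2 libraries. The libraries held 1463976 (WT 4W-Myc Hep replicate 1) to 13738657 (the library labelled WT 4W-Myc Hep replicate 2) UMIs, the tags that mark single captured RNA molecules. After filtering, 46614 cells remained in 41 clusters, of which 37 were named after marker genes and 4, with 2582 cells (5.54%), were left unnamed. The labels do not state that replicates came from separate animals, so the p-values below measure the spread between these libraries.

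Hepatocyte-like cells made up 94.0 to 98.0% of the kept cells of the Hep libraries at 10 days and 96.5% (WT) and 79.4% (SKO) at 0D-Ctrl. At 4W-Myc the hepatocyte-like share was 79.9% in WT replicate 1 and 40.4% in SKO. In the SKO 4W-Myc Hep library, 16.9% of cells were Kupffer cell or macrophage-like, 16.7% endothelial-like and 11.9% oncofetal hepatocyte-like. The library labelled WT 4W-Myc Hep replicate 2 stood apart with 23.3% hepatocyte-like, 22.4% T cell-like and 17.1% B cell-like cells. Unnamed clusters held 0% (WT 10D-Myc) to 7.46% (the library labelled WT 4W-Myc Hep replicate 2) of the Hep libraries. In the NPC libraries the unnamed share ran from 3.38% (WT 10D-Vector) to 21.6% (SKO 10D-Myc).

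Ptpn11 (GRCm38 chromosome 5:121130533-121191397), the gene deleted in SKO hepatocytes, was lower in the SKO hepatocyte-lineage cells of the first 3 stages. Its level in WT was 33.6 CPM (UMI counts scaled to a common total per library) at 0D-Ctrl, 35.7 at 10D-Vector, 27.5 at 10D-Myc and 40.2 in WT 4W-Myc replicate 1. The SKO levels were 15, 9.20, 7.20 and 18.9 CPM at the same stages. The SKO to WT ratios were 0.447 (95% interval 0.333 to 0.591), 0.258 (0.181 to 0.361) and 0.261 (0.176 to 0.378), with intervals that hold counting error only. The library labelled WT 4W-Myc Hep replicate 2 held 7.82 CPM (16 UMIs), below 3 of the 4 SKO libraries and against its WT label. The SKO to WT ratio at 4W-Myc was 0.471 against replicate 1 and 2.42 against the library labelled WT 4W-Myc Hep replicate 2. The position of the deletion is not given in the sources used here, and 3′ tags of Ptpn11 therefore do not check it. Over the stages the edgeR log2 fold change was -1.44 (SE 0.504, adjusted p = 0.654), lower in SKO at 4 of 4 stages. It was -1.73 without the library labelled WT 4W-Myc Hep replicate 2. That library is doubted for its low Ptpn11 level, so leaving it out gives no separate test of Ptpn11.

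**Figure D1:**
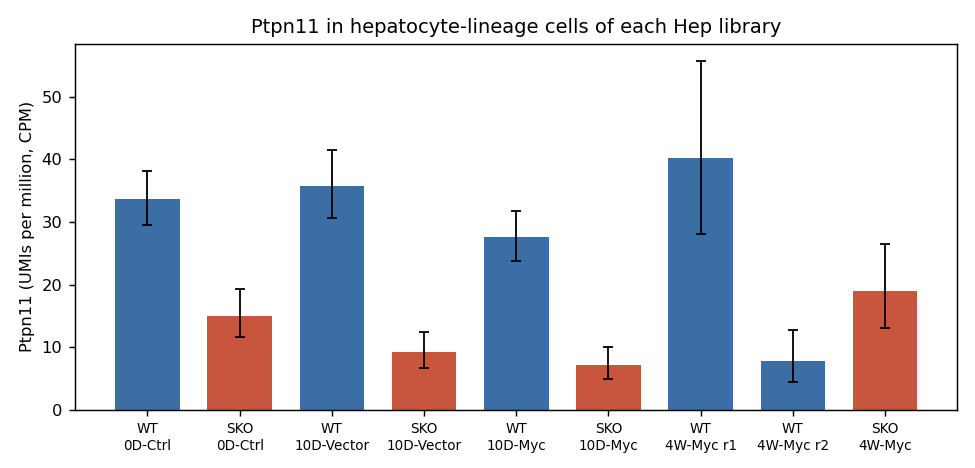
Ptpn11 in the summed hepatocyte-lineage cells of each Hep library (CPM); bars are single libraries and lines are exact 95% Poisson intervals for counting error. WT libraries lay at 27.5 to 40.2 CPM except the library labelled WT 4W-Myc Hep replicate 2 (7.82 CPM), and SKO libraries at 7.20 to 18.9 CPM.

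Cyp7a1, the enzyme that starts bile acid synthesis, was higher in SKO hepatocyte-lineage cells at every stage and passed with all libraries. The drug-metabolizing cytochrome Cyp3a11 and the ornithine aminotransferase Oat, an enzyme of cells near the central vein, were called higher in SKO only without the library labelled WT 4W-Myc Hep replicate 2. Nr0b2, a nuclear receptor that represses Cyp7a1 transcription, and several major urinary protein genes were lower in the same fit. Axin2, a feedback gene of β-catenin signalling, had higher values in SKO at every stage, while Ctnnb1, which encodes β-catenin itself, showed no steady direction.

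In the test over all 9 Hep libraries, 4 of 11277 genes rose in SKO and 0 fell (650 at unadjusted p under 0.05; 127 changed by DESeq2). Cyp7a1 (4:6265612-6275633) rose by log2 5.41 (SE 0.649; adjusted p = 0.0383, DESeq2 adjusted p = 1.58e-20), higher in SKO at 4 of 4 stages. The other 3, named after their values were seen, were Gsn, which was over 10 times as high in an NPC class and is a possible free RNA gene, and H2-Q1 and Acot2, whose mean levels lay below 30 CPM. The count depended on single libraries: it was 296 without the library labelled WT 4W-Myc Hep replicate 2 and 0 without any 1 of the other 8. The real grouping was set among random splits that ignored genotype, 100 in all. Of these 100, 4 called as many genes or more, with the real grouping counted among the 4, and the highest called 4355. A split that calls so many more genes than the real grouping points to structure among the samples.

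Without the library labelled WT 4W-Myc Hep replicate 2, 186 genes rose in SKO and 110 fell, of which 74 are possible free RNA of other cells. Among enzymes of bile acid, drug and fatty acid oxidation, Cyp7a1 rose by log2 5.07 (adjusted p = 7.21e-06), Cyp4a14 by 4.34 (0.00991), Cyp3a11 by 3.58 (0.000536), Cyp2a5 by 3.55 (0.0145) and Cyp2c37 by 1.89 (0.00107). Csad, which makes the taurine used to conjugate bile acids, rose by 4.06 (0.000319), and the organic cation transporter Slc22a3 by 4.01 (0.0027). Aldh3a2, an aldehyde dehydrogenase of lipid breakdown, rose by 3.06 (1.37e-05), the pericentral enzyme Oat by 2.25 (0.000863), and the glutathione transferases Gstm3 and Gstm2 by 3.14 (0.0136) and 2.11 (0.00222). Pdk4, which limits glucose oxidation, rose by 2.18 (0.00784), the peroxisomal thiolase Acaa1b by 1.38 (0.00738) and the sterol synthesis gene Hmgcs1 by 1.45 (0.0085). Each of these genes was higher in SKO at 4 of 4 stages, which the naming rule required except of genes added from a list. No group was replicated in this fit, so its p-values rest on differences between the genotypes in their response to stage alone.

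Several genes of secreted liver proteins fell in the same 8 libraries, although the mature hepatocyte list had 4 genes higher and 2 lower there. The major urinary protein gene Mup11 had log2 -3.64 (adjusted p = 0.0104), Mup16 -2.10 (0.00878) and Mup17 -1.96 (0.0294). Albumin (Alb) had -1.52 (0.0126), the vaspin gene Serpina12 -3.11 (0.0297) and the hepcidin gene Hamp2 -2.26 (0.000247). Nr0b2 had log2 -1.61 (0.00086), the lipogenic regulator Thrsp -1.73 (0.00222), the periportal serine dehydratase Sds -1.95 (0.0349) and the interferon-induced GTPase Iigp1 -1.05 (0.0133). Spry4, an inhibitor of Ras and Erk signalling, had -2.01 (0.0473) but is a possible free RNA gene. All of these genes were lower in SKO at 4 of 4 stages, which the naming rule required except of genes added from a list. The fetal growth factor Igf2 rose by 3.66 (0.0104; 3 of 4 stages), but it is a marker of the oncofetal cluster, which held 22.7% of these cells in SKO 4W-Myc and 6.74% in WT replicate 1. Also higher were Tspan8 (4.28, 0.00784), Sox4 (3.02, 0.00352) and Spp1 (1.96, 0.0134), which are possible free RNA genes.

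**Figure D2:**
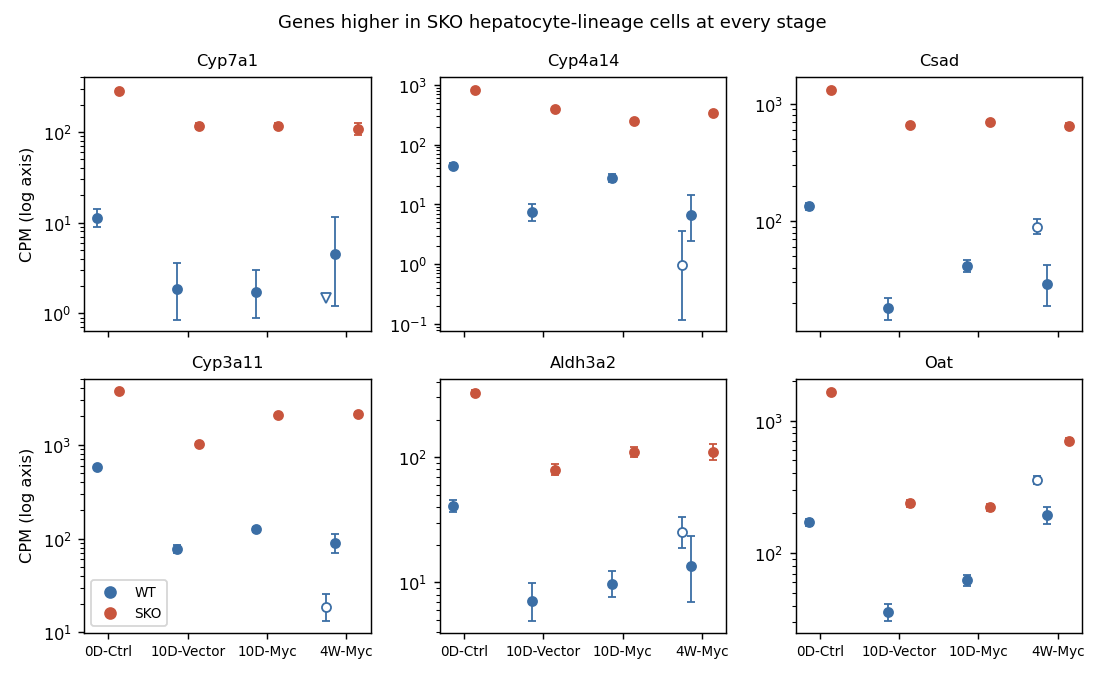
Level of 6 genes in hepatocyte-lineage cells per Hep library (CPM, log axis) by stage in WT (blue) and SKO (red); lines are exact 95% Poisson intervals, open circles mark the library labelled WT 4W-Myc Hep replicate 2 and an open triangle marks 0 UMIs. Cyp7a1 lay at 107.5 to 282.4 CPM in SKO and at most 11.4 CPM in WT.

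The genes followed by name for their role in Myc-driven tumours gave few calls between genotypes. Axin2 (11:108920349-108950783) had log2 2.80 (SE 0.622; edgeR adjusted p = 0.217, DESeq2 0.0155) and 2.47 (0.0133) without the library labelled WT 4W-Myc Hep replicate 2, higher in SKO at 4 of 4 stages. Mouse Myc had 2.35 (adjusted p = 0.467) and 2.96 (0.0149) without that library, but is a possible free RNA gene and was counted in 5 of the 9 Hep libraries without the human MYC feature. Glul, the pericentral glutamine synthetase, had 1.52 (0.568) and 1.34 (0.192) without it. The values for Ctnnb1 were 0.10 (0.980) and -0.07 (0.908), and those for the fetal secreted protein Afp 1.13 (0.956) and 0.77 (0.318). Ccnd1, a cyclin that drives entry into the cell cycle and a possible free RNA gene here, had 0.67 (0.956), the proliferation marker Mki67 1.28 (0.932) and the Y-linked Ddx3y -0.11.

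Tested as gene groups, 6 fixed lists differed between SKO and WT with a preset correlation between genes, and none with an estimated one. The list of β-catenin targets and pericentral genes had a median log2 of 1.56 with 22 of 22 genes positive (adjusted p = 8.01e-23; adjusted p = 0.268 with an estimated correlation). None of its genes passed over all genes tested and 12 passed when adjusted over the list alone, while 10 of 22 passed over all genes without the library labelled WT 4W-Myc Hep replicate 2. By stage the median difference was 1.87 at 0D-Ctrl, 1.06 at 10D-Vector, 0.65 at 10D-Myc and 2.51 at 4W-Myc. Periportal genes, which mark the opposite end of the lobule, had a median of -0.85 with 0 of 20 positive (0.352 with an estimated correlation; 0 genes over all genes or over the list alone). The male-biased list had -0.90 with 2 of 12 positive (0.352; 4 over the list alone).

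The oncofetal list, genes silenced after birth and active in liver cancer, had a median of 0.93 with 12 of 14 positive (adjusted p = 0.352 with an estimated correlation; 5 over the list alone, 0 over all genes). Cell cycle genes had 1.21 with 27 of 29 positive (0.541 with an estimated correlation; 0 genes over all genes or over the list alone), and their stage differences were 1.57, 0.13, 0.12 and 1.90. Kupffer cell identity genes had 0.93 with 7 of 9 positive (0.352; 0 genes), in a class where such transcripts can stem from free RNA. The acute phase list was not called over stages.

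**Figure D3:**
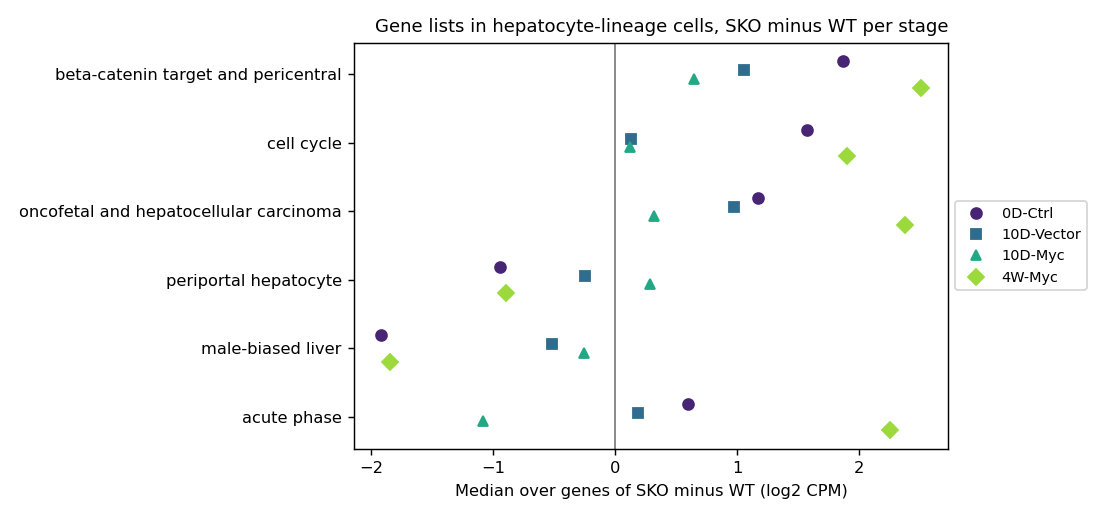
Median SKO minus WT difference in log2 CPM for 6 gene lists in hepatocyte-lineage cells at each stage, each point from 1 library per genotype except WT 4W-Myc, where the mean of 2 libraries was used; no interval is drawn. The list of β-catenin targets and pericentral genes was positive at 4 of 4 stages (0.65 to 2.51) and the acute phase list ran from -1.09 at 10D-Myc to 2.25 at 4W-Myc.

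At each single stage there was 1 library per genotype, except for 2 WT libraries at 4W-Myc, so SKO to WT ratios are given without a test. The 95% intervals, given for the first 3 stages, hold counting error only. The hepatocyte-like class was made of 12 clusters, and 8 of them came mostly from 1 library: 0 and 1 from WT 0D-Ctrl, 15 from SKO 0D-Ctrl, 12, 27 and 28 from WT 10D-Myc, 19 from SKO 4W-Myc and 38 from the library labelled WT 4W-Myc Hep replicate 2. Ratios between genotypes therefore also compare different clusters. At 0D-Ctrl the steroid hydroxylase Cyp2c69 had a ratio of 79.3 (46.0 to 150), the acute phase genes Saa2 and Orm2 had 37.2 (31.5 to 44.4) and 23.9 (19.2 to 30.1), Cyp2a5 25.6 (22.2 to 29.5) and Cyp7a1 24.9 (19.9 to 31.5). Glul had 5.83 (5.42 to 6.27) and Axin2 8.72 (2.92 to 35.1). The G protein regulator Rgs16 had 0.00483 (0.000584 to 0.0175; 2 UMIs in SKO), the steroid enzyme Hsd3b5 0.0159 (0.00683 to 0.0314), Mup7 0.0170 (0.01 to 0.0269) and the protease inhibitor Serpina1e 0.0380 (0.0363 to 0.0396).

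At 10D-Vector, Cyp7a1 had a ratio of 62.2 (32.5 to 137), Cyp4a14 53.1 (38.3 to 76.1), Csad 36.6 (29.6 to 45.9) and Saa2 20.9 (17.8 to 24.8). Lpin1, a phosphatidate phosphatase, had 0.0494 (0.0413 to 0.0587), the metallothioneins Mt1 and Mt2 0.0677 (0.0540 to 0.0841) and 0.103 (0.0690 to 0.148), and the stress gene Herpud1 0.126 (0.111 to 0.142). Mouse Myc had 54.4 (9.35 to 2187), resting on 1 UMI in WT. At 10D-Myc, Cyp7a1 had 67.6 (38.4 to 132), Csad 16.9 (15 to 19.2) and Cyp3a11 16.7 (15.6 to 17.9). The metallothioneins were far lower in SKO there, with 0.00670 (0.00571 to 0.00781) for Mt2 and 0.00924 (0.00842 to 0.0101) for Mt1. The acute phase genes Saa2 and Saa1 had 0.0626 (0.0592 to 0.0660) and 0.114 (0.109 to 0.118), and Glul 1.04 (0.899 to 1.2).

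At 4W-Myc, ratios were taken against WT replicate 1 and then against the library labelled WT 4W-Myc Hep replicate 2, whose Ptpn11 level goes against its label. They were 50.7 and 347 (2 UMIs) for Cyp4a14, 24 and 115 for Cyp3a11, 32.3 and 49.2 for Cyp2a5, 32.5 and 28.4 for Gstm3, and 29.5 and 1415 (1 UMI) for Orm2. Tsku, a secreted inhibitor of Wnt and TGF-β signalling, was at least 112-fold higher (0 UMIs) and 191-fold higher (4 UMIs), and Cyp7a1 24.1-fold (4 UMIs) and at least 73.3-fold (0 UMIs). Glul had 4.43 and 7.79, Ccnd1 5.91 and 4.50, and Afp 2.02 and 36.9. Lower in SKO were Mup16 (0.0333 and 0.00429), Serpina1e (0.0261 and 0.0174), the sulfotransferase Sult2a8 (0.0521 and 0.00825) and Hsd3b5, with 0 UMIs in SKO.

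At 10 days after injection, no gene of hepatocyte-lineage cells passed between the Myc plasmid and the empty vector, in a test of little reach. Axin2 and Mki67 had small positive values and Afp a negative one.

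edgeR called 0 of 11277 genes between 10D-Myc and 10D-Vector over genotypes (40 at unadjusted p under 0.05; DESeq2 called 0), and 0 without any 1 library. Afp had log2 -1.54, Axin2 1.01, Mki67 0.74 and Glul -0.07, each with adjusted p = 1.00. Mouse Myc had no common direction, with 0.208 and 0.574 CPM in WT (1 and 4 UMIs) and 11.3 and 1.69 CPM in SKO (54 and 8 UMIs) at 10D-Vector and 10D-Myc, and only the 10D-Myc libraries of this comparison were counted with the human MYC feature. In 10D-Myc Hep libraries the human MYC feature received 18 UMIs in WT and 14 in SKO. The test had little reach: with a log2 change of 2 added to counts simulated from the data, edgeR recovered 1.00% of genes and DESeq2 22.0%.

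Of the fixed lists, 11 were called with the preset correlation between 10D-Myc and 10D-Vector, none with an estimated one, and in each of them 0 genes passed over all genes or over the list alone. Acute phase genes, secreted by the liver in inflammation, had a median of 0.83 with 23 of 24 positive (adjusted p = 0.449 with an estimated correlation). Myc-linked ribosome biogenesis and growth genes had 0.23 with 24 of 30 positive (0.682), and β-catenin targets and pericentral genes 0.43 with 15 of 22 positive (0.715). Dissociation stress genes had 0.40 with 14 of 20 positive (0.404).

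At 4W-Myc no gene of hepatocyte-lineage cells passed against 0D-Ctrl with all 9 libraries, and the genes below rose or fell once the library labelled WT 4W-Myc Hep replicate 2 was left out. Igf2 and Afp, silent in adult hepatocytes and active in liver tumours, rose, but the summed cells hold the oncofetal cluster named from these genes at 4W-Myc (282 of 1241 cells in SKO and 54 of 801 in WT replicate 1) and none of it at 0D-Ctrl. Pgk1 and Nop56 and Wdr43 of ribosome assembly also rose. Cyp7a1 and Cyp27a1 of bile acid synthesis and the drug-metabolizing Cyp3a11 fell.

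edgeR called 0 of 11277 genes between 4W-Myc and 0D-Ctrl over genotypes (821 at unadjusted p under 0.05; DESeq2 called 83). WT 4W-Myc Hep replicate 1 and SKO 4W-Myc Hep were counted with the human MYC feature, and both 0D-Ctrl Hep libraries without it. Their lowest barcode depths were 246 and 444 UMIs, against 1121 (WT) and 784 (SKO) at 0D-Ctrl. In a fit of these libraries alone for the 2 stages, stage cannot be told apart from how the libraries were counted. Without the library labelled WT 4W-Myc Hep replicate 2, 365 genes rose and 192 fell, of which 164 are possible free RNA, and 0 changed without any 1 of the other libraries. Igf2 (7:142650766-142666816) rose by log2 12.10 (adjusted p = 0.00036) and Afp (5:90490737-90508907) by 5.16 (0.000224), while Afp had 4.59 (SE 1.09; edgeR adjusted p = 0.438, DESeq2 0.00367) with all libraries. In hepatocyte-like cells alone, with all libraries, Afp had 1.6 (0.953) and Nop56 and Wdr43 had 0.39 and 0.61 against 1.86 and 1.44 in the summed cells. Of ribosome and growth genes Nop56 rose by 2.21 (0.0372), Wdr43 by 1.83 (0.0163) and the pyrimidine synthesis gene Cad by 2.05 (0.0391). The glycolytic Pgk1 rose by 1.86 (0.00858), while the glycolysis list had a median of -0.23 in those 8 libraries with 4 genes called higher and 1 lower. Also higher were the serine synthesis gene Psat1 (4.20, 0.00239), the RNA export factor Alyref (2.43, 0.00039), Irf1 (1.74, 0.0246), the p53 target Bbc3 (1.35, 0.0425) and the immediate early gene Egr1 (1.73, 0.0337). Pkm, Hk2, Phgdh, Pmaip1 and Sox9 also rose but are possible free RNA genes.

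Lower at 4W-Myc in those 8 libraries were Mup11 (log2 -5.38, adjusted p = 0.0121), Thrsp (-2.94, 0.000744) and Cyp2c67 (-2.18, 0.0085). Cyp3a11 (-1.99, 0.0414), Cyp27a1 (-1.77, 0.00985), Cyp7a1 (-1.75, 0.0372) and Slc27a5 (-1.50, 0.0213), all of bile acid or drug metabolism, fell as well. Aldh3a2 (-1.81, 0.00672), the clotting gene F2 (-1.87, 0.00603), Cyp2e1 (-1.38, 0.0419) and the lipogenic Me1 (-1.38, 0.0428) also fell. Every gene named here moved in the same direction in WT and in SKO, which the naming rule required except of genes added from a list. Glul had -1.96 (0.518), Myc 1.93 (0.708), Ccnd1 1.2 (0.773), Mki67 1.15 (0.812), Axin2 0.87 (0.860) and Ctnnb1 -0.32 (0.934) with all 9 libraries.

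As groups in all 9 libraries, cell cycle genes had a median of 1.15 at 4W-Myc with 29 of 29 positive (adjusted p = 0.237 with an estimated correlation; 0 genes over all genes, 1 over the list alone). Myc-linked ribosome biogenesis and growth genes had 0.71 with 28 of 30 positive (0.237; 0 and 0), and oncofetal genes 1.71 with 11 of 14 positive (0.237; 0 and 3). Mature hepatocyte genes had -0.97 with 5 of 26 positive (0.237; 0 and 0), bile acid genes -1.07 with 0 of 18 positive (0.237; 0 and 0) and β-catenin targets and pericentral genes -0.80 with 4 of 22 positive (0.237; 0 and 2). Ras and Erk feedback genes had 0.64 with 13 of 15 positive, and lipogenesis genes -0.69 with 5 of 20 positive, both with 0.237 with an estimated correlation and 0 genes over all genes (2 and 0 over the list alone). Lists of other cells and of cell handling moved alongside, all with 0.237: dissociation stress 0.93 (16 of 20 positive), sinusoidal endothelial identity 1.44 (12 of 12), inflammatory macrophage 1.67 (7 of 8) and mitochondrially encoded genes -1.86 (4 of 13). Without the library labelled WT 4W-Myc Hep replicate 2, 6 dissociation stress and 2 inflammatory macrophage genes were called higher and, of mitochondrially encoded genes, 3 were called lower and 1 higher.

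At 10 days after the empty vector injection, Oat, Cyp2c37 and Aldh3a2, which were also among the genes raised in SKO, were lower in hepatocyte-lineage cells than at 0D-Ctrl in the 8 libraries whose Ptpn11 level fits their label. Oat and Aldh3a2 were 2 of the 22 β-catenin target and pericentral genes tested, and no other gene of that list was called there. Glul, the strictest pericentral gene, had a negative value that did not pass.

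edgeR called 0 of 11277 genes between 10D-Vector and 0D-Ctrl over genotypes (154 at unadjusted p under 0.05; DESeq2 called 6). Without the library labelled WT 4W-Myc Hep replicate 2, 3 genes rose and 8 fell, and 0 changed without any 1 of the others. Aldh3a2 had log2 -2.26 (adjusted p = 0.0116), Cyp2c37 -2.33 (0.0186) and Oat -2.55 (0.0262), lower in both genotypes. With all libraries Glul had -1.83, Axin2 -1.24, Mki67 -1.84 and Afp 1.90, each with adjusted p = 1.00. The list of β-catenin targets and pericentral genes had a median of -1.65 with 0 of 22 positive (adjusted p = 0.201 with an estimated correlation; 0 genes over all genes, 6 over the list alone). Interferon response genes had -0.73 with 5 of 21 positive (0.239; 0 and 1), cell cycle genes -0.90 with 3 of 29 positive (0.548; 0 and 0) and periportal genes 0.63 with 19 of 20 positive (0.548; 0 and 0).

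A cluster of 482 cells appeared almost only at 4W-Myc and was named oncofetal hepatocyte-like from markers that include Afp and Igf2, so those genes are not results for it. Its leading genes also held noncoding transcripts such as Gm26917, Rn7sk and Rpph1, and whether these reflect the quality of its RNA was not tested. Its share of hepatocyte-lineage cells was 22.7% in SKO 4W-Myc Hep (282 of 1241 cells; 95% interval 20.4 to 25.2%) and 6.74% in WT 4W-Myc replicate 1 (54 of 801; 5.10 to 8.71%). It was 0 of 1235 cells (exact upper limit 0.298%) in the library labelled WT 4W-Myc Hep replicate 2, 0.488% in SKO 10D-Myc (10 of 2048) and 0 in the other Hep libraries. In the NPC libraries it held 111 of 2624 cells (4.23%) of WT 4W-Myc replicate 1, 20 cells (0.834%) of SKO 4W-Myc, 2 of 2060 cells of WT 4W-Myc replicate 2, 2 of 2740 cells of SKO 10D-Myc and 1 of 783 cells of WT 0D-Ctrl. No difference between genotypes was tested in the Hep libraries. Over the stages of the NPC libraries its share of all kept cells had a mean log-odds of 0.107 for SKO over WT (exact permutation p = 0.792). Directions by stage are not counted here. At 10D-Vector neither NPC library held such a cell, and at 4W-Myc the SKO share lay between those of the WT replicates.

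Transcripts of the human MYC transgene lay mostly in these cells at 4W-Myc. The feature received 99 UMIs in WT 4W-Myc replicate 1, 97 of them in oncofetal cells, and 110 in SKO 4W-Myc, 97 of them (88.2%) there, 7 in hepatocyte-like and 5 in endothelial-like and Kupffer cell-like cells. Of oncofetal cells, 63.0% (48.7 to 75.7%) held a human MYC UMI in WT replicate 1 and 23.8% (18.9 to 29.2%) in SKO. Hepatocyte-like cells held one in 0.268% and 0.626% of cells. As a measure of free RNA, endothelial-like and Kupffer cell-like cells held one in 0 of 62 cells (exact upper limit 5.78%) in WT replicate 1 and 0.627% of 797 in SKO. Median depths were 1171.5 UMIs (WT replicate 1) and 887 (SKO) in oncofetal cells, and 701 and 782 in endothelial-like and Kupffer cell-like cells. Summed over oncofetal cells the feature reached 1144 CPM in WT replicate 1 and 285 CPM in SKO. At 10D-Myc, where nearly all cells were hepatocyte-like, these held 17 of 18 UMIs in WT (2.44 CPM, with 1 UMI in 50 endothelial-like and Kupffer cell-like cells at 14.2 CPM) and 11 of 14 in SKO (2.34 CPM). The other 3 UMIs in SKO lay in the 10 oncofetal cells (182 CPM).

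**Figure D4:**
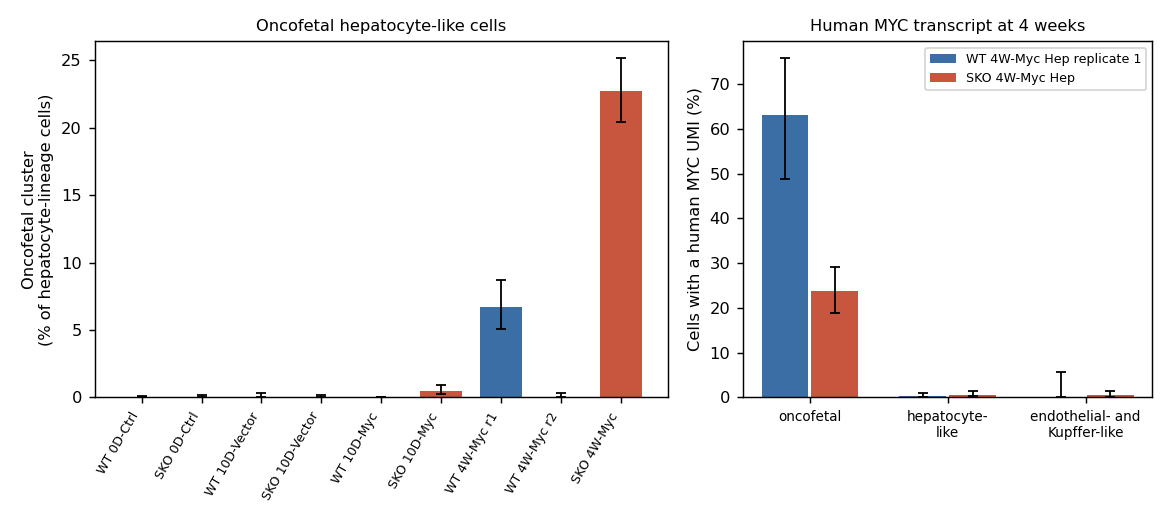
Left, oncofetal hepatocyte-like share of hepatocyte-lineage cells per Hep library (%); right, share of cells with a human MYC UMI (%) in oncofetal, hepatocyte-like and endothelial-like plus Kupffer cell-like cells of the WT 4W-Myc replicate 1 and SKO 4W-Myc Hep libraries, with exact 95% binomial intervals. The cluster held 22.7% of hepatocyte-lineage cells in SKO 4W-Myc and 6.74% in WT replicate 1, and the MYC feature was found in 63.0% (WT) and 23.8% (SKO) of its cells.

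Within oncofetal cells, 148 genes had enough counts for an SKO to WT ratio at 4W-Myc, without a test. The hepcidin gene Hamp had 8.98 (4.50 to 21), the acute phase gene Orm1 8.90 (2.96 to 43.8; 3 UMIs in WT), Apoc4 of lipid transport 6.76 (3.9 to 12.8) and Gstm1 6.07 (3.14 to 13.5). The mitochondrial tRNA synthetase Lars2 had 0.378 (0.303 to 0.472) and Jund 0.602 (0.486 to 0.748). Ccnd1, a possible free RNA gene, reached 144 CPM in hepatocyte-like cells of SKO 4W-Myc, a library rich in endothelial-like and macrophage-like cells, and 22.2 CPM (18 UMIs) in those of WT replicate 1. Gpc3, a cell-surface proteoglycan of liver cancer, reached 29.4 CPM (10 UMIs) in SKO oncofetal cells and 0 in WT replicate 1.

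Cells with transcripts of G2 and mitosis were counted after thinning every cell to 1000 UMIs. In SKO 4W-Myc, 6.57% of hepatocyte-lineage cells (41 of 624; 617 shallower cells left out; 7.01% unthinned) carried at least 2 such UMIs. The share was 3.15% in WT 4W-Myc replicate 1 (10 of 317; 484 left out; 2.0% unthinned) and 0.162% in the library labelled WT 4W-Myc Hep replicate 2 (2 of 1235; none left out; 0.324% unthinned). At 0D-Ctrl it was 2.44% in SKO (34 of 1393; 835 left out; 2.69% unthinned) and 0.215% in WT (7 of 3252; none left out; 0.277% unthinned). At 10 days every share lay between 0.0835% and 0.330%, with 716 shallower cells of SKO 10D-Vector, 4757 of WT 10D-Myc and 909 of SKO 10D-Myc left out (unthinned 0.137 to 0.584%). B cell-like and T cell-like cells, used as a measure of free RNA, reached 0.225% against 0.856% in hepatocyte-lineage cells (median depth 1702.5 UMIs against 1640). Of the B cell-like and T cell-like cells, 2090 of 2226 came from the library labelled WT 4W-Myc Hep replicate 2. They reached 0.191% there, against 0.162% in its hepatocyte-lineage cells. After thinning to 1000 UMIs, SKO 4W-Myc held 19, WT replicate 1 held 1 and SKO 0D-Ctrl held 38, too few to measure free RNA there. Unthinned, the 2 pooled shares were nearly alike at 0.926% and 0.993%, and with at least 1 UMI they were 2.29% and 2.38%. Free RNA is therefore not set apart at any of these settings. The mean log-odds of SKO over WT was 1.29, higher in SKO at 3 of 4 stages (exact permutation p = 0.167).

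In several immune classes of the NPC fraction, single immediate early genes were lower 10 days after vector injection than at 0D-Ctrl, but many of these calls were lost without the cell barcodes shared between libraries, and in dendritic cell-like and monocyte-like cells the counts fell from 19 to 1 and from 46 to 4. Dusp1, which shuts off stress kinases, was lower in B, NK and plasmacytoid dendritic cell-like cells with and without these barcodes. Kept calls are limited by Xist that remained in the WT 0D-Ctrl NPC library after the removal, as given below. Jun and Fos, transcription factors switched on within minutes of cell stress, kept their calls only in plasmacytoid dendritic cell-like cells (Jun) and NK cell-like cells (Fos), and the chemokine gene Ccl3 lost its calls in T cell-like and monocyte-like cells. Lyz2, the lysozyme of mature myeloid cells, rose in monocyte-like cells. Rn7sk, a noncoding RNA that restrains transcription elongation, fell in NK cell-like and T cell-like cells.

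edgeR called 13 of 6503 genes between 10D-Vector and 0D-Ctrl in B cell-like cells (6 higher), 23 of 4726 in NK cell-like (5 higher), 20 of 9685 in T cell-like (1 higher) and 19 of 8424 in dendritic cell-like cells (2 higher). In monocyte-like cells it called 46 of 6381 (8 higher) and in plasmacytoid dendritic cell-like cells 73 of 6086 (38 higher). Of these genes 6, 1, 0, 1, 4 and 4 in the same order of classes are possible free RNA. The 0D-Ctrl NPC libraries shared 410 cell barcodes with each other where 1.96 were expected by chance. Xist, the RNA of the inactive X chromosome, fell with a fitted log2 of -11.30 in T cell-like (edgeR adjusted p = 0.000101) and -8.46 in NK cell-like cells (0.0062). Both 10D-Vector NPC libraries held 0 Xist UMIs, so the size of these values depends on how the fit treats a count of 0. Of the Xist UMIs of the 0D-Ctrl libraries, 91.8% lay under shared barcodes. With shared barcodes removed, the counts were 13, 12, 7, 1, 4 and 45. Such barcodes were 37.2% of those in the WT and 32.7% of those in the SKO 0D-Ctrl NPC library. A call lost without them can therefore stem from fewer cells as well as from a smaller change. Removal was also incomplete in the WT 0D-Ctrl NPC library. Its unshared barcodes held Xist at 37.9 CPM (92 UMIs) and the pigment-cell gene Dct at 58.1 CPM, against 0.737 and 0.983 CPM in SKO. A call kept without shared barcodes can therefore still rest in part on such cells. Single libraries moved the counts too: they were 123, 147, 59, 207, 155 and 165 without WT 4W-Myc NPC replicate 1 and 0, 9, 8, 3, 3 and 14 without WT 0D-Ctrl NPC. They were 3, 11, 9, 4, 5 and 14 without SKO 10D-Vector NPC, 21, 18, 8, 20, 4 and 3 without WT 10D-Vector NPC, 31, 30, 43, 47, 37 and 42 without SKO 4W-Myc NPC, and 4, 23, 29, 9, 29 and 40 without SKO 0D-Ctrl NPC. Without WT 4W-Myc NPC replicate 2 the B cell-like count was 31, and the NK cell-like count was 38 and 39 without the SKO and the WT 10D-Myc NPC library.

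In NK cell-like cells, Rn7sk had log2 -4.91 (adjusted p = 0.000151; 0.000409 without shared barcodes), Dusp1 -4.25 (0.000182; 0.00311), Fos -4.59 (4.23e-05; 0.029) and the chemokine receptor Cxcr4 -3.44 (0.00865; 0.0254). Jun had -3.80 (4.23e-05) but 0.121 without shared barcodes, and the stress gene Ppp1r15a -2.73 (0.00232) but 0.128. In T cell-like cells Rn7sk (-5.24, 0.000125; 0.000313) and Cxcr4 (-2.72, 0.00342; 0.00466) stayed called, while Jun (-3.42, 0.000758), Tnfaip3 of NF-κB feedback (-2.52, 0.00664) and Ccl3 (-5.74, 0.0309) had 0.129, 0.129 and 0.316. In B cell-like cells Dusp1 (-3.90, 0.0457), the histone demethylase Kdm6b (-2.88, 0.00672) and the chaperone Dnajb9 (-2.76, 0.0146) all kept their calls. Each gene named here had the same direction in WT and in SKO, which the naming rule required except of genes added from a list.

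In monocyte-like cells the stress gene Ier3 had log2 -4.51 (adjusted p = 0.00267; 0.0144 without shared barcodes), the cytokine Osm -5.56 (0.00496) and the prostaglandin enzyme Ptgs2 -5.13 (0.00659), the latter 2 with too few counts for the test without shared barcodes. Jun (-3.18, 0.00503) and Ccl3 (-3.12, 0.0131) lost their calls without shared barcodes (0.127 and 0.0677). Lyz2 rose by 1.19 (0.00324; 0.0168). In dendritic cell-like cells Atf3, a stress transcription factor, had -4.30 (0.000475) but 0.127 without shared barcodes, and the interferon-induced Cxcl10 -4.34 (0.011) but 0.223. In plasmacytoid dendritic cell-like cells Dusp1 (-3.42, 0.00649; 0.016), Cxcr4 (-2.84, 0.00374; 0.00583), Jun (-2.17, 0.00253; 0.00795), Ier2 (-2.08, 0.00253; 0.00359) and Junb (-1.85, 0.01; 0.016) kept their calls, and Fos (-3.18, 0.00556) did not (0.326). The monocyte chemokine receptor Ccr2 rose by 1.31 (0.0213) and the transcription regulator Id3 by 1.87 (0.0101).

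**Figure D5:**
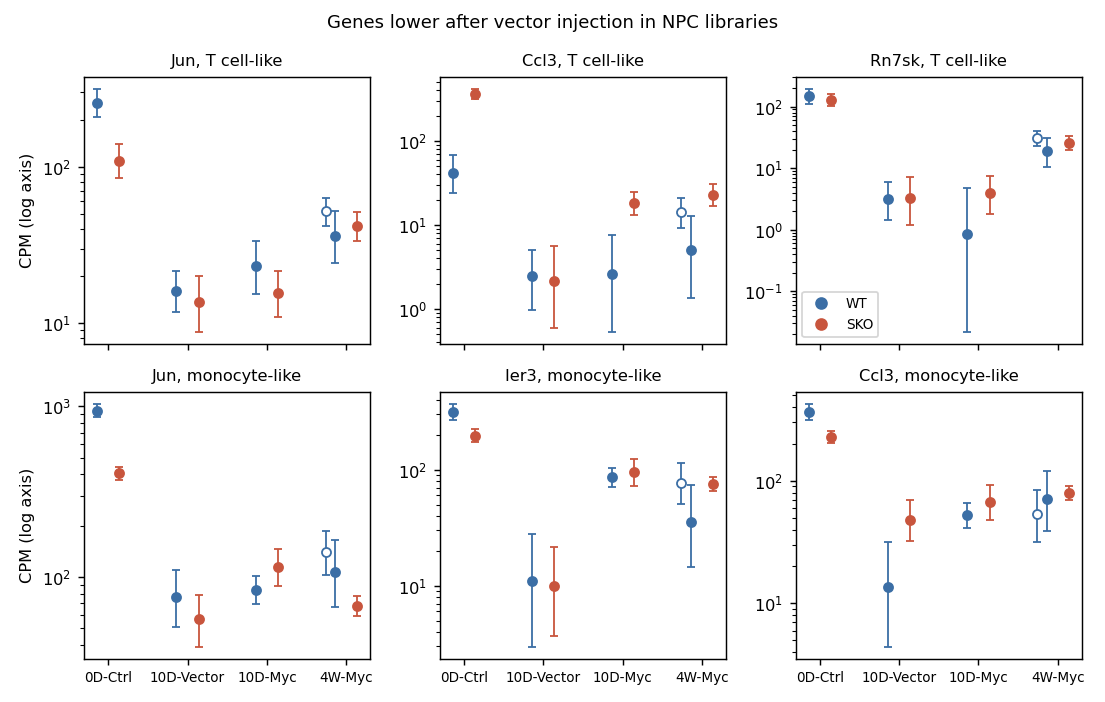
Level of Jun, Ccl3 and Rn7sk in T cell-like cells and of Jun, Ier3 and Ccl3 in monocyte-like cells per NPC library (CPM, log axis) by stage in WT (blue) and SKO (red); lines are exact 95% Poisson intervals. From 0D-Ctrl to 10D-Vector, the log2 change of Rn7sk was -5.24 in T cell-like cells and that of Ier3 -4.51 in monocyte-like cells.

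The dissociation stress list, genes induced while tissue is digested, was lower at 10D-Vector than at 0D-Ctrl in all 6 immune classes. These list tests kept the cells of shared barcodes, without which many calls of single genes were lost. At resolution 2.0 an unnamed cluster of 131 cells was led by Xist and also by Fos, Atf3, Osm and Ptgs2. The lower list values are therefore not read as an effect of the injection. Its median in T cell-like cells was -2.17 with 1 of 19 positive (adjusted p = 0.0465 with an estimated correlation; 2 genes over all genes, 18 over the list alone). In NK cell-like cells it was -1.89 with 0 of 16 positive (0.108 with an estimated correlation; 4 and 14), and in monocyte-like cells -2.08 (0.101; 8 and 19 of 19). B cell-like, dendritic cell-like and plasmacytoid dendritic cell-like cells had -1.81 (0.12; 1 and 7), -1.62 (0.0787; 2 and 15) and -1.85 (0.0712; 6 and 10). Ras and Erk feedback genes had -1.17 in NK cell-like cells with 0 of 9 positive (0.0409; 2 and 4) and -1.44 in T cell-like cells with 3 of 12 positive (0.0465; 0 and 8). Inflammatory macrophage genes had -1.50 in T cell-like cells with 1 of 9 positive (0.0465; 1 and 5). In dendritic cell-like cells, cell cycle genes had 1.00 with 23 of 29 positive (0.0787; 12 over the list alone).

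Between 4W-Myc and 0D-Ctrl, edgeR called 0 genes in B cell-like cells (374 at unadjusted p under 0.05; DESeq2 called 7), 5 in NK cell-like, 5 in T cell-like, 8 in dendritic cell-like, 30 in monocyte-like and 11 in plasmacytoid dendritic cell-like cells. Without shared barcodes the counts were 0, 1, 2, 0, 1 and 10, and without WT 0D-Ctrl NPC they were 0, 0, 1, 0, 2 and 1. Without 1 of the other libraries they ran from 0 to 6, 6 to 14, 1 to 18, 4 to 18, 6 to 43 and 1 to 34. Rn7sk had log2 -2.74 in NK cell-like (adjusted p = 0.00203) and -2.33 in T cell-like cells (0.0223), and 0.0069 and 0.0388 without shared barcodes. In monocyte-like cells Osm (-3.18, 0.00719), Jun (-2.70, 0.00614), Egr1 (-2.48, 0.0226) and Ccl3 (-2.06, 0.0365) fell, but Jun, Egr1 and Ccl3 each had 1.00 without shared barcodes and Osm was then too low to test. In plasmacytoid dendritic cell-like cells the chemokine receptor Cxcr3 (-1.84, 0.0336), the protease Ctsl (-1.12, 0.0336) and the MHC class I genes H2-D1 (-0.84, 0.0336) and H2-T23 (-0.94, 0.0407) fell. MHC class I genes as a list had -0.58 there with 0 of 15 positive (0.239 with an estimated correlation; 7 over the list alone).

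Between genotypes, and between 10D-Myc and 10D-Vector, few genes passed in immune cells. For SKO against WT, edgeR called 1 gene in NK cell-like cells, Mup3 (log2 -2.60, adjusted p = 0.0143, DESeq2 0.0698), a hepatocyte gene and possible free RNA, whose call was lost without the SKO 4W-Myc or the WT 10D-Vector NPC library. It called 0 in B, T, dendritic, monocyte-like and plasmacytoid dendritic cell-like cells (240, 411, 364, 308 and 255 at unadjusted p under 0.05; DESeq2 called 0, 0, 2, 0 and 0). The plasmacytoid dendritic cell-like count was 9 without SKO 0D-Ctrl NPC and 6 without WT 0D-Ctrl NPC, and without any 1 library it ran from 0 to 3 in NK cell-like cells and was at most 2 in B, T, dendritic and monocyte-like cells. Mitochondrially encoded genes had a median between -0.44 and -0.78 in the 6 classes (adjusted p from 0.513 to 0.946 with an estimated correlation). For 10D-Myc against 10D-Vector, edgeR called 0 genes in each of the 6 classes (121 to 268 at unadjusted p under 0.05; DESeq2 called 2 in monocyte-like cells and 0 in the others). Smaller changes can be missed: of genes given a log2 change of 1 in simulated counts, edgeR recovered 36 to 56% between genotypes, and between 10D-Myc and 10D-Vector from 1% (dendritic cell-like) to 41% (plasmacytoid dendritic cell-like). Endothelial-like cells, tested in the 7 NPC libraries of the injected mice as a fit added after the counts of cells were seen, had 1 of 4829 genes lower in SKO (edgeR adjusted p = 0.00739; 363 at unadjusted p under 0.05; DESeq2 called 2). They had 0 for 10D-Myc against 10D-Vector (89 at unadjusted p under 0.05; DESeq2 called 1).

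None of 17 class shares in the NPC libraries passed the test between SKO and WT, which had little reach with a smallest possible p of 0.0417 before correction. The smallest exact permutation p was 0.0833, for stellate or fibroblast-like cells (mean log-odds -1.39). NK cell-like cells had 0.496 (exact p = 0.125; higher in SKO at 3 of 4 stages), B cell-like cells -0.316 (exact p = 0.292), Kupffer cell or macrophage-like cells -0.798 (exact p = 0.292; higher at 0 of 4 stages; -0.387 and 1 of 4 stages without WT 4W-Myc NPC replicate 1, and -1.21 without replicate 2) and T cell-like cells 0.0616 (exact p = 0.833). The NK cell-like and T cell-like shares leave out an unnamed cluster of 1487 cells led by Trdc, whose closest class by markers was NK cell. Of its cells, 34.5% lay in SKO 10D-Myc NPC and 21.1% in SKO 10D-Vector NPC. At resolution 2.0 a cluster led by Trdc was named NK cell-like, so these shares depend on the naming. Monocyte-like cells were 22.2% of SKO 4W-Myc cells and 3.51% and 3.40% of the WT 4W-Myc libraries, untested at that stage. Kupffer cell or macrophage-like cells were 14.1% and 0.583% of the 2 WT 4W-Myc NPC libraries. Endothelial-like cells were under 1% of both 0D-Ctrl NPC libraries (0.639% and 0.788%) and 11.6% and 14.6% at 10D-Vector.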

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

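The tests of pattern A other than that of shared barcodes in the same cluster, and the test of a wrong label in pattern B, were chosen after results were seen, and the others were written down before their values were computed. Pattern A was the presence of Xist, transcribed from the inactive X chromosome of females, and of pigment-cell genes in the 0D-Ctrl libraries beside the Y-linked Ddx3y. Of the Xist UMIs of the 0D-Ctrl libraries, 91.8% lay under barcodes found in more than 1 of them, and 99.0% of barcodes shared by the 0D-Ctrl NPC libraries fell in the same cluster in both, so the same cells were likely counted in more than 1 library. In the NPC libraries, Xist under unshared barcodes reached 5.07% of its level under shared barcodes, 12.4% in WT and 0.274% in SKO. A female donor of the SKO library is therefore unlikely, and Xist alone did not decide for the WT library. Ddx3y under unshared barcodes had 44.5 CPM in WT and 51.1 CPM in SKO, against 2.66 and 6.32 CPM under shared barcodes. These values argue against a female donor as the only source of the unshared WT cells, among which 92 Xist UMIs remained. Free RNA is an unlikely source, since barcodes with Xist were at least 5.96 times as frequent among shared barcodes, and whether the sharing arose in sequencing or in the preparation was not tested.

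Pattern B was the distance of the library labelled WT 4W-Myc Hep replicate 2 from the other 4W-Myc Hep libraries, and its fraction label, with 23.3% hepatocyte-like and 22.4% T cell-like cells, was not tested. Counting without the human MYC feature is an unlikely explanation, as the feature took at most 0.0111% of hepatocyte-lineage UMIs elsewhere. Oncofetal cells in replicate 1 only are also unlikely, since leaving them out changed the spread by 1.00%. For free RNA of immune cells, 7.19% of the 709 genes at least 4-fold apart from replicate 1 had an NPC class over 10 times the hepatocyte level. However, 370 of these genes were higher in replicate 1, which free RNA in the other library cannot raise. The hepatocyte level also included the library labelled WT 4W-Myc Hep replicate 2. The test therefore cannot decide for the 339 genes higher in that library. A swapped or wrong genotype label remains possible. Its Ptpn11 level of 7.82 CPM lay below every other WT library (lowest 27.5). Its rank correlation with SKO 4W-Myc was 0.209 below that of replicate 1 (difference -0.209). That difference reflects how near replicate 1 lay to SKO 4W-Myc (0.900). The doubted library had 0.691 with SKO 4W-Myc and 0.683 with replicate 1, so correlation places it with neither genotype. The library held 0 UMIs of Cyp7a1, 2 of Cyp4a14 and 1 of Orm2, against 193, 609 and 1241 in SKO 4W-Myc. At 4W-Myc, however, genes were named only where both WT libraries lay on the same side of SKO. These low counts therefore do not by themselves test the label. Of the 296 genes that changed without this library, 36.1% lay nearer to the SKO mean in it, below the 40% set as the limit for a right label. The share was 21.5% of genes higher and 60.9% of genes lower in SKO. Since both directions were then required to lie on 1 side, the test could not decide.

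Pattern C was the higher level of β-catenin targets and pericentral genes in SKO hepatocyte-lineage cells. Oncofetal cells in the sum are an unlikely explanation, since the median log2 was 1.66 with hepatocyte-like cells alone, and depth per cell is unlikely, since it was 1.60 with cells thinned to 1000 UMIs. A larger recovery of pericentral cells was examined in cells whose periportal share of UMIs lay at or above the WT median. Their SKO to WT ratios were 5.59 at 0D-Ctrl, 2.24 at 10D-Vector, 1.66 at 10D-Myc and 3.15 at 4W-Myc. In all cells they were 3.88, 3.06, 1.89 and 2.12. The ratio at 4W-Myc rests on 25 SKO cells (752 to 1496 at the other stages). Periportal genes were themselves lower in SKO (0 of 20 positive), so the change partly decides which cells were compared. The test therefore cannot decide whether recovery played a part or was the whole cause.

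The real grouping of genotypes is counted among the splits given here. As many genes as in it, or more, were called in 4 of 100 splits of the Hep libraries (real 4, highest 4355). For NK cell-like cells this held in 15 of 40 splits (real 1, highest 130). In the B, T, dendritic, monocyte-like and plasmacytoid dendritic cell-like classes the real count was 0, so 40 of 40 splits reached it by construction. The highest counts there were 295, 201, 324, 125 and 65. The highest split of the Hep libraries put both 10D-Vector libraries with WT 4W-Myc replicate 1 and SKO 4W-Myc, and that of each NPC class put both 10D-Vector libraries with WT 4W-Myc replicate 2 and SKO 4W-Myc. Since stage is in the model, these splits by construction compare only the library labelled WT 4W-Myc Hep replicate 2 with the other 4W-Myc Hep libraries, and WT 4W-Myc NPC replicate 1 with the other 4W-Myc NPC libraries.

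The acute phase list had opposite directions between SKO and WT at 4W-Myc (2.25) and 10D-Myc (-1.09), apart by 3.34, and this was not tested. Haemoglobin genes in hepatocyte-lineage cells had 3.84 at 10D-Vector and -2.03 at 0D-Ctrl (apart by 5.88), untested, and the cause was not tested. Their change from 10D-Vector to 10D-Myc was 0.54 in WT and -2.12 in SKO (apart by 2.65), and from 0D-Ctrl to 10D-Vector 1.15 in SKO and -4.80 in WT (apart by 5.95), both untested. Mitochondrially encoded genes changed from 0D-Ctrl to 10D-Vector by 0.58 in WT and -1.04 in SKO (apart by 1.62), also untested. The human MYC feature received only 18 and 14 UMIs at 10D-Myc in WT and SKO and 99 and 110 at 4W-Myc in WT replicate 1 and SKO, and the cause was not tested.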

How the results depend on the processing

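Choices were fixed before the data were examined, except the fits without shared barcodes, without both 0D-Ctrl libraries, the endothelial-like fit over 7 libraries and the oncofetal share at other settings, which were chosen after results were seen. Over the 34 answers to comparisons, 390 alternative values stayed within the limit for the same result and 210 moved. For named genes 4337 alternative values gave the same call, 300 a stronger and 804 a weaker one, and 43 reversed direction. For the gene lists 835 gave the same call, 2 a stronger and 427 a weaker one, and for the shares of cells 125 gave the same call and 8 reversed direction. Of single-stage values 89 stayed and 31 moved. No paired analysis was possible because only the WT 4W-Myc Hep and NPC libraries share replicate numbers and the 2 fractions were not compared in a test. Endothelial-like and Kupffer cell or macrophage-like cells could not be tested over all 9 NPC libraries, since the 0D-Ctrl NPC libraries held fewer than 20 of them. Where a group lost its only library, the remaining libraries were assumed to vary alike.

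Counts of changed genes follow the order SKO against WT, 10D-Myc against 10D-Vector, 4W-Myc against 0D-Ctrl and 10D-Vector against 0D-Ctrl where 4 values are given. DESeq2 called 127 (SKO against WT), 83 (4W-Myc) and 6 (10D-Vector) genes in hepatocyte-lineage cells, 7 (4W-Myc) and 40 (10D-Vector) in B cell-like, 0 (SKO against WT) and 37 (10D-Vector) in NK cell-like, and 16 (4W-Myc) and 56 (10D-Vector) in T cell-like cells. It called 2 (SKO against WT) and 47 (10D-Vector) in dendritic cell-like cells, 2 (10D-Myc), 47 (4W-Myc) and 74 (10D-Vector) in monocyte-like cells and 28 (4W-Myc) in plasmacytoid dendritic cell-like cells. In endothelial-like cells DESeq2 called 2 (SKO against WT) and 1 (10D-Myc).

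Without a filter on low counts the calls were 194, 9, 229 and 9 in hepatocyte-lineage cells, 3, 11, 63 and 160 in B cell-like, 10, 5, 34 and 103 in NK cell-like and 16, 3, 66 and 206 in T cell-like cells. They were 19, 6, 115 and 343 in dendritic cell-like, 14, 29, 129 and 247 in monocyte-like and 10, 2, 34 and 147 in plasmacytoid dendritic cell-like cells. With a mean of at least 30 CPM they fell to 0 for SKO against WT in hepatocyte-lineage cells. At 10D-Vector they were then 4 in B cell-like, 9 in T cell-like, 10 in dendritic cell-like, 25 in monocyte-like and 25 in plasmacytoid dendritic cell-like cells, and at 4W-Myc 1 in T cell-like, 2 in dendritic cell-like and 4 in monocyte-like cells. Library-size scaling gave 1 (4W-Myc) and 21 (10D-Vector) in B cell-like cells, 46 and 35 (10D-Vector) in T cell-like and dendritic cell-like cells and 21 (4W-Myc) in plasmacytoid dendritic cell-like cells.

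With the feature list as a covariate the hepatocyte-lineage counts were 316, 3830, 4487 and 17. The covariate separates the library labelled WT 4W-Myc Hep replicate 2 from the other 4W-Myc libraries, so by construction 4W-Myc against 0D-Ctrl then rests on that library and 10D-Myc against 10D-Vector on its distance from replicate 1. With this covariate the 4W-Myc against 0D-Ctrl log2 values turned to -1.77 for Lars2, -2.54 for Yam1, -0.51 for Alyref, -0.40 for Prpf4b, -0.0690 for Snhg9, -0.53 for Klf10, 0.51 for Thrsp, 1.72 for Fabp2, -1.65 for Cad, -1.58 for Egr1, -2.06 for Sox9, -1.29 for Zmat3, -1.18 for Phgdh, -3.42 for Pdia4, -0.12 for Klf6 and -3.00 for mt-Nd6. The SKO against WT value of Ctnnb1 turned to -0.0727. With hepatocyte-like cells alone, Lars2 and Yam1 turned to -1.07 and -0.82. Fabp2 turned to 0.18 by DESeq2, 0.0387 with library-size scaling and 0.10 with at least 1000 UMIs per cell. Acaa1b turned to -0.11 without a filter, -0.0484 with at least 30 CPM and -0.0531 with thinned cells.

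Thinning cells to 1000 UMIs gave at 4W-Myc 2 in B cell-like, 3 in NK cell-like, 3 in T cell-like, 5 in dendritic cell-like and 4 in plasmacytoid dendritic cell-like cells, at 10D-Vector 6 and 12 in the latter classes and 0 for SKO against WT in NK cell-like cells. Without doublet removal, and at cluster resolutions 0.5 and 2.0, that NK cell-like count was also 0. Resolution 0.5 gave 10 (4W-Myc) and 37 (10D-Vector) in NK cell-like, 2 (4W-Myc) in T cell-like and 2 (4W-Myc) and 7 (10D-Vector) in dendritic cell-like cells. Resolution 2.0 gave 3 (4W-Myc) in NK cell-like, 33 (10D-Vector) in dendritic cell-like and 1, 3, 1 and 5 in monocyte-like cells. With at most 20% mitochondrial UMIs 32 genes were called at 10D-Vector in dendritic cell-like cells. Without shared barcodes the counts were 1 (4W-Myc) and 12 (10D-Vector) in NK cell-like, 2 and 7 in T cell-like, 0 and 1 in dendritic cell-like, 1, 1, 1 and 4 in monocyte-like and 45 (10D-Vector) in plasmacytoid dendritic cell-like cells. Without both 0D-Ctrl libraries SKO against WT gave 0 in hepatocyte-lineage, 2 in NK cell-like, 1 in monocyte-like and 4 in plasmacytoid dendritic cell-like cells, where 10D-Myc against 10D-Vector gave 1. Of the gene lists 236 of 632 tests were called with the preset correlation, 4 with an estimated correlation and 43 by fry.

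Leaving out 1 library at a time, the counts ran from 0 to 296 (SKO against WT), 0 to 557 (4W-Myc) and 0 to 11 (10D-Vector) in hepatocyte-lineage cells, with each highest value found without the library labelled WT 4W-Myc Hep replicate 2. They ran from 0 to 2, 0 to 1, 0 to 6 and 0 to 123 in B cell-like, 0 to 3, 0 to 3, 0 to 14 and 9 to 147 in NK cell-like and 0 to 1, 0 to 1, 1 to 18 and 8 to 59 in T cell-like cells. They ran from 0 to 1, 0 to 0, 0 to 18 and 3 to 207 in dendritic cell-like, 0 to 1, 0 to 1, 2 to 43 and 3 to 155 in monocyte-like and 0 to 9, 0 to 2, 1 to 34 and 3 to 165 in plasmacytoid dendritic cell-like cells. Named genes ran from -0.0711 to 0.325 (Ctnnb1) and -0.11 to 1.08 (Ccnd1) for SKO against WT, and from -2.53 to 0.84 (Fabp2), -1.96 to 1.23 (Bhmt) and -1.57 to 0.84 (Acaa1b) for 4W-Myc against 0D-Ctrl.

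Shares of cells in NPC libraries between SKO and WT, as mean log-odds, turned to -0.000553 for T cell-like, -0.109 for hepatocyte-like and -0.116 for plasma cell-like cells without both 0D-Ctrl libraries. Without 1 WT 4W-Myc replicate they ran from -0.00203 to 0.125 for T cell-like, -0.133 to 0.797 for mesothelial cell-like, -0.343 to 0.557 for oncofetal hepatocyte-like, -0.14 to 0.358 for plasma cell-like and -0.437 to 0.113 for plasmacytoid dendritic cell-like cells. The G2 and mitosis log-odds of hepatocyte-lineage cells was 0.750 with at least 1 UMI (exact permutation p = 0.25), 1.21 without thinning (exact p = 0.167) and 0.923 with cells thinned to 500 UMIs (exact p = 0.375), and from 1.03 to 1.45 over 10 draws of the thinning to 1000 UMIs.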

Other observations

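The tests in this part were chosen after the results were seen. Ptpn11 in SKO 4W-Myc was 2.65 times as high in oncofetal as in hepatocyte-like cells (95% interval 1.22 to 5.54; 13 and 21 UMIs), against 1.2 (0.307 to 3.37; 4 and 32 UMIs) in WT replicate 1. The WT interval holds the SKO ratio, so no difference between the genotypes is shown. The level in SKO oncofetal cells was 38.2 CPM, on few UMIs in 1 SKO library. Since 3′ tags of Ptpn11 do not check the deletion, the test cannot decide whether these cells kept the gene. A study that sorts these cells and genotypes the deletion would decide it.

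Mouse Myc reached 2278 CPM in oncofetal cells of the SKO 4W-Myc NPC library and 440 CPM in those of WT 4W-Myc NPC replicate 1, both counted without the human MYC feature, against 5.88 and 11.8 CPM in the Hep libraries counted with it. The gene lists differ between these libraries, and whether reads of the transgene were assigned to mouse Myc where the human feature was not listed was not tested. Mouse Myc in libraries counted without the feature is therefore not read here as the endogenous gene.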
